A study of Homo sapiens with 18 samples.

How the data were processed

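The series measured messenger RNA (RNA-seq) and the histone mark H3K27me3 (ChIP-seq, with input libraries) in SKOV3, a human epithelial ovarian cancer cell line, in wild-type cells and in cells labelled as EZH2 knockout. The labels describe 18 samples in 6 groups of 3. The knockout was made with CRISPR/Cas9, a nuclease that cuts DNA at a guide-directed site, per the labels' protocols. RNA libraries were made from polyadenylated RNA with a stranded kit and sequenced on an Illumina instrument, per the labels' protocols.

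The deposited table holds raw read counts per gene, made by the authors with HTSeq on genome build hg38, per the submitters' processing notes. The RNA-seq aligner, the annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, overlapping and antisense genes cannot be told apart with certainty, and near-identical copies, such as AKR1C1, AKR1C2 and AKR1C3, KRT14 and KRT17, the HLA genes and SPANXB1, are uncertain where the counting could split their reads. The table has 26485 rows. A spreadsheet had turned 28 gene names into dates, and these rows held 0.259% of the counts and are named nowhere. 4 rows had a repeated name, and 6036 rows had 0 counts in all libraries used. No row lacked a gene name.

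Of the 6 columns, 5 matched RNA samples by name: knockout replicates 1, 2 and 3 and wild-type replicates 2 and 3. 1 column matched no labelled sample and was used in no step. Wild-type replicate 1 was not analysed here, so the comparison was 3 knockout against 2 wild-type libraries where 3 against 3 had been planned. The ChIP-seq and input samples were not analysed here. All knockout libraries carry the same clone name, so the effect of the genotype and any property of that clone are confounded. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

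Total counts were 17666427, 18738087 and 17998208 in knockout replicates 1, 2 and 3, and 23270621 and 18241877 in wild-type replicates 2 and 3. Genes were kept by filterByExpr and scaled by TMM in edgeR 4.0.16 (R 4.3.3), which left 14917 genes. They were tested 2-sided with edgeR's quasi-likelihood test, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold and 3 residual degrees of freedom. CPM values are counts scaled to a library of 1e+06 counts, computed here with TMM scaling, given as mean ± SD. Log2 fold changes are knockout over wild type, given ± SE. This SE was derived from the test, as the size of the log2 fold change over the square root of its F statistic. It was not estimated directly. For a gene with 0 counts over all libraries of a genotype, the fold is a lower bound computed against a floor of 3 counts over that genotype. With 1 to 3 counts, it is a ratio with its 95% exact binomial interval. These bounds and intervals cover counting error only.

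Gene lists fixed before the data were examined, 47 in number, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over the 46 lists with at least 3 tested members. The remaining list, mRNAs of the mitochondrial genome, had 0 members in the table. Alternatives were camera with an estimated correlation and fry. The former rests on 3 residual degrees of freedom, so few lists or runs could pass adjustment. Positions came from RefSeq genes on GRCh38.p14, to which 25135 rows (94.9%) were matched by name. Camera was also run over 291 runs of about 50 neighbouring genes. Runs called with a median log2 fold change of at least 0.3 in size are termed shifted. The rule for named genes, also fixed beforehand, took EZH2, the 12 genes with the largest and the 12 with the smallest log2 fold change among called genes with a symbol, a mean CPM of at least 1 and no overlap between genotypes, up to 4 genes per list by p, and any member of the Polycomb repressive complex 2, sterol biosynthesis and mevalonate lists. Members named for a list in which no gene is called were those with the highest CPM. Genes fixed for a test in the closing section are named there too. Departing from the rule as fixed, XIST and Y-linked genes were left out of naming as a precaution with human samples, so the 12 genes in each direction are those taken after leaving them out, and a gene with a larger change than those named can be missing. Some other genes that the rule takes are not reported here. Counts and list tests include all of these genes.

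Other scalings, filters, a replicate block, DESeq2 1.42.0, limma-voom and leaving out each library were tried. Steps were tested on simulated data with the dispersions and library sizes of the knockout and wild-type libraries. Of 14664 simulated genes tested, those changed 1.5-fold were recovered in 72% of cases, those changed 2-fold in 91.8%, 4-fold in 98% and 8-fold in 100%. Unchanged genes made up 6.3% of the 190 calls. The simulation changed only 200 genes, while 55.7% of tested genes were called in the data, so these rates may not carry over.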

Results

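RNA-seq read counts were compared between 3 libraries of SKOV3 cells labelled as EZH2 knockout and 2 libraries of wild-type SKOV3 cells. EZH2 is the catalytic subunit of Polycomb repressive complex 2, which methylates histone H3 at lysine 27, and the series title links its loss to steroid biosynthesis and tumorigenicity. Depth ranged from 17666427 to 23270621 counts per library. Libraries of the same genotype correlated at r of 0.992 to 0.993 in log2 CPM across genes and those of different genotypes at 0.925 to 0.927, where genes are not independent replicates. No pair of libraries agreed within sampling noise, the mean chi-square per gene being at least 2.95 where sampling alone gives about 1.

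EZH2 transcripts were present in both genotypes. EZH2 (chromosome 7, 148807383 to 148884291, GRCh38.p14) measured 52.6 ± 1.18 CPM in the knockout (n = 3) and 57.5 ± 7.41 CPM in the wild type (n = 2), a log2 fold change of -0.13 ± 0.080 that did not pass the test (edgeR adjusted p = 0.155). The value depended on the wild-type libraries: it was 0.0046 without wild-type replicate 2 and -0.26 without wild-type replicate 3, the latter with an adjusted p of 0.033. A count over a whole gene neither shows nor excludes a small CRISPR deletion or insertion, so it does not check the genotype labels. Among 13 tested subunits of Polycomb repressive complex 2, 2 rose and 6 fell. PHF19 (0.34 ± 0.067) and LCOR (0.52 ± 0.12) rose, and the core subunit SUZ12 (-0.40 ± 0.072), the EZH2 paralog EZH1 (-0.43 ± 0.096) and the histone chaperone RBBP4 (-0.42 ± 0.071) fell. EED, another core subunit, had a log2 fold change of 0.10 ± 0.093. The list as a whole was not called by camera (adjusted p = 0.327). PHF19 and LCOR both lie in chromosome runs that shifted upward and EZH1 in a run that shifted downward, and of the 10 subunits outside shifted runs, a check chosen after seeing the data, 0 rose and 5 fell by edgeR. Of these 5, PHF1, RBBP7 and JARID2 lost their calls in 6, 3 and 1 of 14 other settings.

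Large differences separated the genotypes. Of 14917 genes tested, 4123 were higher and 4191 lower in the knockout, together 55.7%, with a median size of 0.54 on the log2 scale among those called. Which direction held more genes depended on the scaling, with 4357 higher and 3962 lower using library size only and 4690 higher and 3691 lower with upper-quartile scaling. At least 2-fold differences were found for 1185 higher and 940 lower genes. Among the genes with the largest rise were the zinc finger gene ZNF536 (at least 331-fold higher, 24.2 ± 1.39 CPM against 0 counts), the Polycomb group gene SFMBT2 (ratio 740, 95% interval 132 to 29200) and the calcium channel gene CACNA1C (at least 25.8-fold higher). Among those with the largest fall were the estrogen receptor gene ESR1 (at least 360-fold lower, 19.8 ± 0.046 CPM in the wild type), the calcium-binding protein gene CALB1 (at least 1410-fold lower), the retinol carrier gene RBP4 (ratio 2490, 95% interval 447 to 98500) and the keratin genes KRT14 (at least 599-fold lower) and KRT17 (ratio 8120, 95% interval 1460 to 321000). In each of these genes the libraries of the genotypes did not overlap. The number of genes lower by at least 2-fold was 605 under a filter of 1 CPM in at least 3 libraries, a filter that genes expressed only in the 2 wild-type libraries cannot pass.

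Genes of sterol synthesis moved in both directions. Of 15 tested genes of the steps after farnesyl diphosphate, 8 rose and 4 fell, and adjusted over the list alone the counts were the same. DHCR7, which makes cholesterol in the last step of a branch of the pathway, rose from 96.1 ± 7.87 to 185.9 ± 5.98 CPM (log2 fold change 0.96 ± 0.067), and the lanosterol synthase gene LSS (0.72 ± 0.060) and NSDHL (0.60 ± 0.072) also rose. The sterol isomerase gene EBP fell from 12.3 ± 0.78 to 2.97 ± 0.80 CPM (-2.06 ± 0.17), and SC5D (-1.04 ± 0.063), TM7SF2 (-0.79 ± 0.15) and MSMO1 (-0.65 ± 0.075) fell as well. The list had a median log2 fold change of 0.24 and a mean of -0.035, and camera did not call it (adjusted p = 0.464). In the mevalonate pathway 4 of 10 tested genes rose and none fell by edgeR, with the same counts adjusted over the list alone. HMGCS1 (0.54 ± 0.060), IDI1 (0.42 ± 0.072) and PMVK (0.45 ± 0.097) were among those that rose. Its median was 0.23 and camera did not call it either (adjusted p = 0.322). The fry test, which asks only whether a list's genes move on balance one way, gave adjusted p = 0.0013 for the first list and 0.0032 for the second, both upward. The series title names steroid biosynthesis, and how the study chose that theme is not given in the sources used here, so the lists may not be independent evidence. Of those counted as higher, HSD17B7 (0.34 ± 0.14, adjusted p = 0.043) lost its call in 8 of 14 other settings, among them DESeq2, limma-voom, no low-count filter and the fits without either wild-type library, with log2 fold changes from 0.27 to 0.35. SQLE lost its call without wild-type replicate 2 (0.20, adjusted p = 0.076) and FDFT1 without wild-type replicate 3 (0.20, adjusted p = 0.059).

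**Figure D1:**
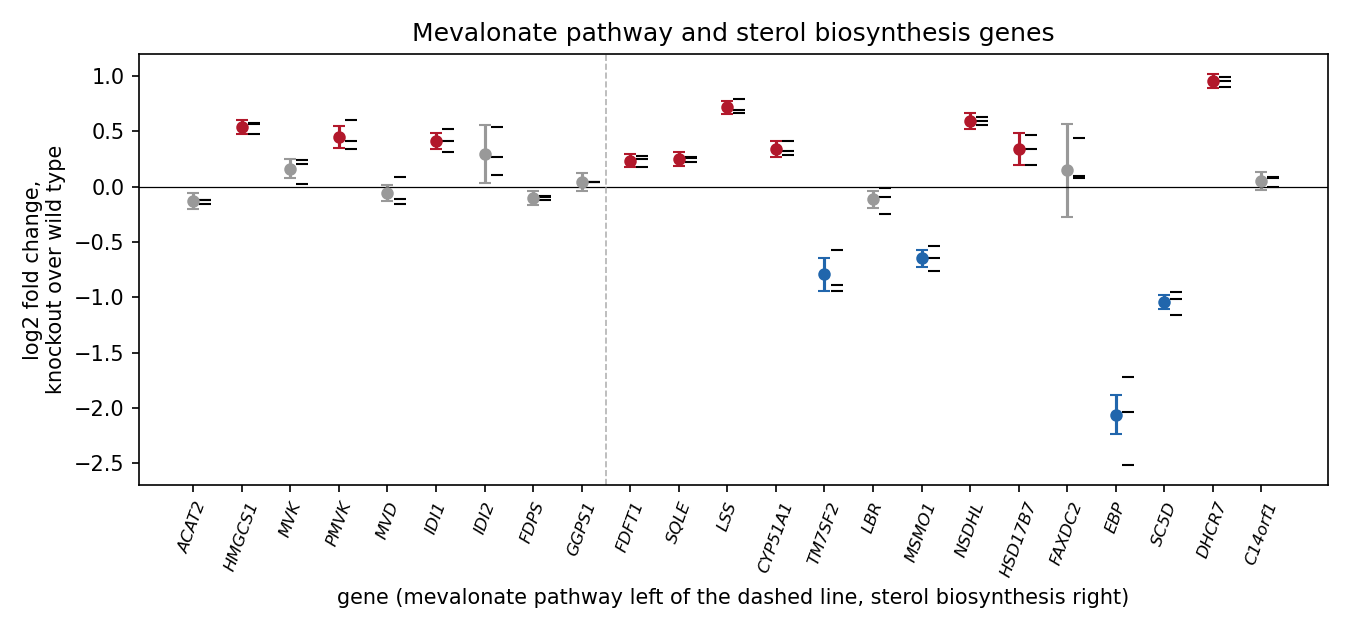
Log2 fold change of knockout over wild type (vertical axis) for tested genes of the mevalonate pathway and of sterol biosynthesis that are reported here (horizontal axis). Points are edgeR estimates with SE as error bars, red for genes that rose, blue for genes that fell and grey for genes not called, and dashes are single knockout libraries against the wild-type mean. In the sterol biosynthesis list 4 genes lie below 0 as called, EBP lowest at -2.06.

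Genes around this pathway also differed. In sterol sensing and uptake, 9 of 16 genes rose and 4 fell, with the regulator gene SREBF1 (1.00 ± 0.089) and the lysosomal lipase gene LIPA (1.30 ± 0.087) among those that rose. In steroid hormone metabolism 3 of 18 rose and 8 fell. The aldo-keto reductase genes AKR1C1 (-5.30 ± 0.11), AKR1C2 (-5.47 ± 0.16) and AKR1C3 (-3.03 ± 0.084), near-identical copies whose reads may be split, fell, as did CYP1B1 (-1.43 ± 0.055). Camera called neither list (adjusted p = 0.309 and 0.0605).

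Genes known as Polycomb targets moved in both directions. Of 72 tested developmental transcription factor genes, 33 rose and 20 fell. LHX2 (3.58 ± 0.18) and SOX7 (2.49 ± 0.12) rose, GATA4 rose from 2 counts in the wild type (ratio 206, 95% interval 56.7 to 1700), and SOX17 fell from 128.9 ± 14.6 to 27.5 ± 5.39 CPM. Their median was 0.29 and camera did not call the list (adjusted p = 0.263). Of 28 HOX genes, 6 rose and 8 fell, HOXC8 rising (2.01 ± 0.20) and HOXB5 (-1.15 ± 0.098), HOXB6 (-0.96 ± 0.069) and HOXB8 (-0.76 ± 0.069) falling. The HOX median was -0.12 and the mean 0.14, and camera gave an adjusted p of 0.769. Counts adjusted over the list alone were the same for both lists. The fry test gave 0.019 upward for the developmental genes and 0.041 downward for the HOX genes, and most of the 46 lists also passed it. Among 24 genes described in the literature as silenced through EZH2, 5 rose and 14 fell (camera adjusted p = 0.13), with ALDH1A1 higher (5.70 ± 0.26) and IGFBP3 lower (-1.12 ± 0.052).

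Epithelial genes fell. Of 33 tested epithelial genes, 23 fell and 6 rose, with a median of -1.71 (camera adjusted p = 2.91e-05, and adjusted p = 0.216 with an estimated correlation). Adjusted over the list alone, 24 fell and 6 rose. The keratin KRT7 fell from 1285 ± 30.3 to 15.5 ± 1.33 CPM, KRT8 from 942.5 ± 13.1 to 84.4 ± 2.46 CPM and KRT5 from 178.5 ± 2.45 to 4.99 ± 0.38 CPM. Mesenchymal genes went both ways, with 13 of 35 higher and 15 lower (camera adjusted p = 0.696), and COL1A2 (-4.62 ± 0.14) and FBN1 (-2.10 ± 0.067) lower. Markers of mesothelium, another cell type, also went both ways, with 3 of 7 higher and 3 lower (adjusted p = 0.833). Of 7 endothelial markers 2 rose, and of 5 leukocyte markers 1 rose, with no fall called in either (adjusted p = 0.309 and 0.437).

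DNA replication genes fell together. Of 36 genes, 29 fell and 0 rose by edgeR, with the same counts adjusted over the list alone and a median of -0.47 (camera adjusted p = 1.62e-05, and adjusted p = 0.216 with an estimated correlation). POLE (-0.72 ± 0.062), LIG1 (-0.74 ± 0.070) and MCM5 (-0.68 ± 0.064) were among them. Mitosis genes were not called as a list, with 5 of 33 higher and 11 lower (adjusted p = 0.268). Cell cycle inhibitors, D cyclins and RB family genes were mixed, with 5 of 13 higher and 5 lower and a median of -0.18 (camera adjusted p = 0.799). The cyclin-dependent kinase inhibitor genes CDKN1A (1.61 ± 0.13) and CDKN1C (1.37 ± 0.099) rose, and the cyclin gene CCND1 (-1.23 ± 0.064) and the growth inhibitor gene BTG1 (-1.01 ± 0.11) fell.

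Interferon-stimulated and inflammatory genes fell. Of 39 interferon-stimulated genes, 27 fell and 2 rose, with a median of -0.88 (camera adjusted p = 0.000127, and adjusted p = 0.216 with an estimated correlation), BST2 falling from 78.9 ± 0.73 to 4.92 ± 1.15 CPM. Of 36 NF-kB and cytokine genes, 22 fell and 7 rose (adjusted p = 0.00212, and adjusted p = 0.216 with an estimated correlation), with CXCL1 (-4.16 ± 0.083) and CXCL8 (-2.98 ± 0.095) lower and TNFAIP2 (1.31 ± 0.066) higher. Adjusted over the list alone, 23 of the latter fell. Of 15 MHC class I genes, 11 fell and 3 rose (adjusted p = 0.027, and adjusted p = 0.606 with an estimated correlation), with HLA-B at -1.06 ± 0.058 and the regulator gene NLRC5 at -1.34 ± 0.077. Without genes in shifted chromosome runs, an alternative chosen after seeing the data, the calls of the NF-kB and MHC class I lists ended. The NF-kB list lost 11 of its 36 genes, and its median went from -0.92 to -0.31 (mean -1.02, SD over genes 1.72, to mean -0.76, SD 1.88; adjusted p = 0.248). The MHC class I list lost only NLRC5, and its median stayed at -0.37 with 10 of 14 genes lower. Its mean went from -0.392 (SD 0.498) to -0.325 (SD 0.44) and its unadjusted p from 0.0041 to 0.011, which no longer passed after adjustment (adjusted p = 0.0904).

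Genes of ERBB receptor signalling fell. SKOV3 is known for amplification of ERBB2, the gene of the receptor HER2. ERBB2 fell from 3031 ± 34.0 to 700.9 ± 52.2 CPM (-2.11 ± 0.057). Of 30 ERBB and MAPK genes, 21 fell and 2 rose (adjusted p = 1.62e-05, and adjusted p = 0.216 with an estimated correlation), with DUSP4 (-4.72 ± 0.15) and PHLDA1 (-2.01 ± 0.065) lower and the ligand gene HBEGF (2.24 ± 0.091) higher. Of 13 genes of the ERBB2 amplicon, 10 fell and 2 rose (adjusted p = 0.00778, and adjusted p = 0.606 with an estimated correlation), including GRB7 (-3.32 ± 0.13) and MIEN1 (-1.33 ± 0.057). No list of the 46 was called upward by camera with the preset correlation. With an estimated correlation none was called, the lowest camera adjusted p being 0.216. That version rests on 3 residual degrees of freedom, so its lack of calls cannot decide whether gene correlation undid the calls. The estimated correlation was below the preset 0.01 for the epithelial (-0.013), DNA replication (0.0026), interferon (-0.0091) and NF-kB (-0.021) lists. It was above 0.01 for the ERBB and MAPK (0.020), MHC class I (0.17) and ERBB2 amplicon (0.11) lists. For 36 of the 46 lists the counts adjusted over the list alone equalled those over all genes.

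Neighbouring genes shifted together along several chromosomes. Of 291 runs of about 50 genes, 92 were called by camera with the preset correlation, 41 upward and 51 downward. With an estimated correlation 0 were called, but that test rests on 3 residual degrees of freedom and could hardly pass any run. A run of chromosome 4 with 47 of 50 genes lower had camera adjusted p = 2.55e-13 with the preset and 0.379 with the estimated correlation. All 11 runs of chromosome 4 fell, with medians from -0.91 to -0.60. The first run of chromosome X (276356 to 15854813, GRCh38.p14) had a median of -1.09, with 42 of its 50 genes lower. The spread (SD) of run medians was 0.247, against at most 0.085 in 1000 shuffles of gene positions. Among the genes named above, CXCL1, CXCL8 and MSMO1 lie on chromosome 4, LSS lies in a run of chromosome 21 with a median of 0.45, and ERBB2, GRB7, MIEN1, KRT14 and KRT17 lie in a run of chromosome 17 with a median of -0.51. EZH1 (run median -0.45), NLRC5 (-0.50), BTG1 (-0.39) and PHLDA1 (-0.37) also lie in called runs that fell by at least 0.3. PHF19 (0.36), LCOR (0.30), LIPA (0.48) and HBEGF (0.33) lie in called runs that rose by at least 0.3. Called runs with smaller medians hold further genes named above. KRT7, KRT8 and KRT5 (-0.26), POLE (-0.285) and SOX17 (-0.21) fell in runs that fell, and LHX2 (0.20) and CACNA1C (0.17) rose in runs that rose. SQLE (-0.205) and TNFAIP2 (-0.24) rose in runs that fell. RBP4 fell in a run that rose (0.30).

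**Figure D2:**
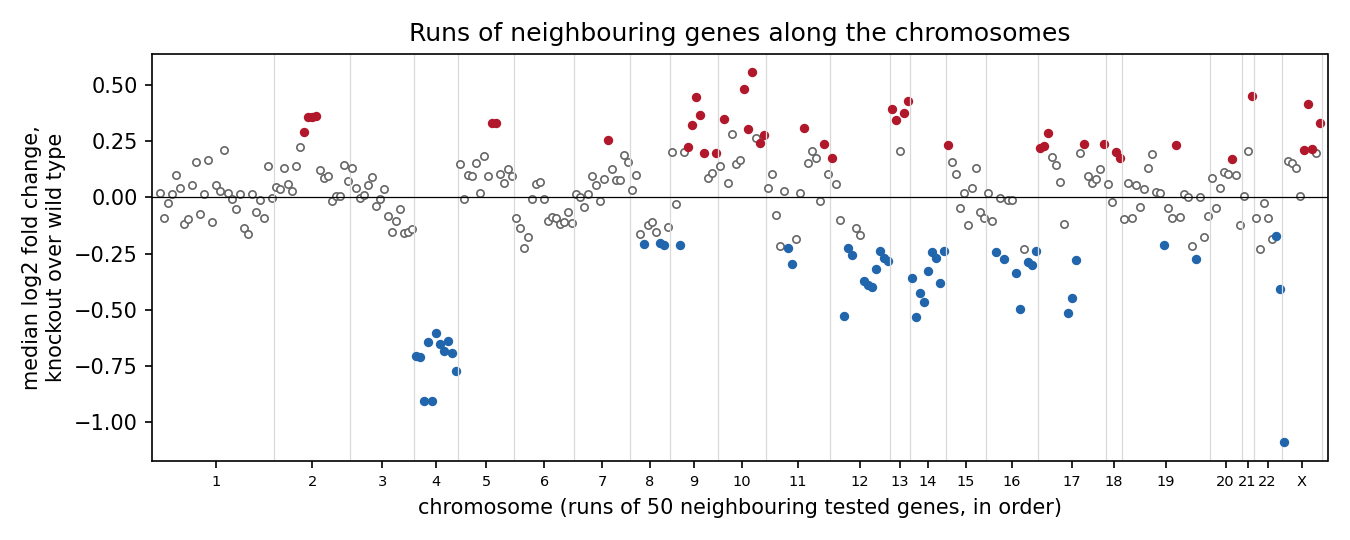
Median log2 fold change of knockout over wild type (vertical axis) for each run of about 50 neighbouring tested genes, in order along chromosomes 1 to 22 and X (horizontal axis). Filled points are runs called by camera with the preset correlation, red upward and blue downward, and open points are runs not called. All 11 runs of chromosome 4 lie between -0.91 and -0.60.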

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

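The filter of at least 1 CPM in 2 libraries and the list tests without genes in shifted chromosome runs were chosen after seeing the data, and the other alternatives before the data were examined. Between 6420 genes (without wild-type replicate 2) and 8381 genes (upper-quartile scaling) were called, and every gene shared with the main calls kept its direction under the 14 other settings of the gene test. More genes were lower (4191) than higher (4123) in the main analysis, and more were higher with library size only (4357 against 3962), upper-quartile scaling (4690 against 3691) and the filter of 1 CPM in 3 libraries (3878 against 3868). DESeq2 called 7309 genes, all among the 8314. Genes lower by at least 2-fold numbered 605 under the filter of 1 CPM in 3 libraries, which genes expressed only in the 2 wild-type libraries cannot pass, and 815 under 1 CPM in 2 libraries. The EZH2 log2 fold change ranged from -0.2594 to 0.0046 when single libraries were left out, reversing without wild-type replicate 2 and passing the test without wild-type replicate 3, and a lone wild-type library is then assumed to vary like the others. Under fry the adjusted p was 0.001304 for sterol biosynthesis, 0.003214 for the mevalonate pathway, 0.01937 for developmental transcription factors and 0.04136 for HOX genes, where camera called none. Fry tests a list by itself, and camera compares it with other genes. The HOX list reversed with no low-count filter (adjusted p = 0.9487), and its adjusted p ranged from 0.6725 to 0.9046 when single libraries were left out, reversing at the latter, without wild-type replicate 3. The direction of 4 uncalled lists was opposite under fry: fatty acid oxidation (adjusted p = 0.2404), angiogenesis (0.01216), ATF4 and unfolded protein response (0.04009) and replication histones (0.1838). For EZH2 and these reversals the cause was not tested. Without genes in shifted runs, the NF-kB (0.2483) and MHC class I (0.09044) lists lost their calls, the median going from -0.92 to -0.31 in the former and from -0.372 to -0.369 in the latter, and no ERBB2 amplicon gene was left to test. Of 2389 values for 172 named genes other than EZH2, 2362 kept direction and side of the threshold. The rest kept direction and lost the call, in RBBP7, JARID2, PHF1, FDFT1, SQLE, HSD17B7 and PGAP3. A gene that a filter removed has no value in that setting, and the filter of 1 CPM in 3 libraries gave values for 155 of the 172. With replicate number as a replicate block, 7635 genes were called, 7421 of them shared. Deviations of same-numbered libraries from their genotype's mean correlated at -0.058 (replicate 2) and 0.003 (replicate 3). The 2 wild-type libraries deviate by equal and opposite amounts, so these values cannot decide whether the numbers pair the samples. With 3 against 2 libraries, camera with an estimated correlation rests on 3 residual degrees of freedom. Its lack of calls therefore cannot decide whether lists or runs shifted. Other splits of the samples were not counted, since the wild type has 2 libraries.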

Other observations

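The tests of chromosome 4, of copy number for the sterol genes that fell and of on-off genes with 2 knockout libraries were chosen only after the results were seen. Neuron and synapse genes included several of the genes that rose most. Of 20 tested, 9 rose and 5 fell, with the adhesion gene NCAM1 rising from 0.31 ± 0.29 to 57.2 ± 2.12 CPM and the receptor gene GABRA3 from 2.36 ± 0.047 to 27.3 ± 1.02 CPM, but camera did not call the list (adjusted p = 0.309). Imprinted genes rose in 11 and fell in 4 of 18 (adjusted p = 0.168). The drug efflux pump gene ABCB1 rose from 0.19 ± 0.034 to 7.56 ± 1.23 CPM and ABCC3 from 47.1 ± 1.67 to 159.3 ± 4.07 CPM, while the drug response list was mixed, with 7 of 29 higher and 8 lower (adjusted p = 0.837).

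More than 50% of tested genes differed between the genotypes, which share their split with a single clone name. Of the genes with a 2-fold change, 23.4% (95% exact interval 21.6 to 25.3) lay in called runs of neighbouring genes shifted by at least 0.3, which held 16.7% of genes. This falls short of the 50% set for copy number acting on neighbours as the whole cause, although the interval reaches past the 25% bound set against it. Only 2-fold changes were counted, and the median shift of chromosome 4, -0.70, is itself under 2-fold. The share therefore cannot decide the cause of the smaller changes, which make up most calls. For the 531 genes of chromosome 4 the median was -0.70, with 395 called lower and 34 called higher. Of these genes 86.3% lay below 0, against 49% on the other autosomes. The medians of genes of low, middle and high expression were -0.48, -0.76 and -0.74. The low class thus lay just outside the bound of 0.2 from the overall median. A wider bound that was also considered (every class below -0.3 and within 0.3 of each other) would have been met. A lower copy number may explain these genes but is left open. Of 168 genes at 3 counts or fewer over a genotype and called, 58.9% were on in the knockout. This share (95% exact interval 51.1 to 66.4, exact binomial p = 0.025) was short of the 60% set for release of silent genes. The floor of 3 counts covered 3 knockout but only 2 wild-type libraries, so it was easier to reach in the wild type. The binomial test against 50% is therefore biased upward, and it treats genes as independent. With any 2 of the 3 knockout libraries the share was 50.3% to 52.1%. Effects of EZH2 loss and of the clone cannot be told apart for the on-off genes in these libraries.

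Keratin and other epithelial genes fell in the knockout. Fibroblasts in the cultures are argued against, since 3 of 5 abundant fibroblast transcripts (COL3A1, DCN and LUM) stayed under 1 CPM in every knockout library, although COL1A1 was at 504.6 ± 40.8 CPM. The median of 5 core genes of the ERBB2 amplicon was -1.33, which meets the bound set beforehand for replacement of SKOV3 by another line, yet a subclone with fewer copies may give the same value, PGAP3 in that core had 0.15 ± 0.065, and ERBB2 stayed above 98.9% of tested genes in every knockout library. For the deletion around CDKN2A known in SKOV3, the bound set beforehand against a line without it was met, since 1 of 3 genes there (CDKN2B) was under 0.1 CPM in all libraries. That bound was set wrongly and decides nothing: CDKN2B had 0 counts in both genotypes, as a silent gene without a deletion also would, and MTAP had 1095 counts in the knockout and 975 in the wild type, so it marked no deletion in either. CDKN2A had 0 counts in the knockout against 8 in the wild type, which decides nothing for the same reason. Replacement, a subclone and an effect of EZH2 loss therefore stay open.

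Sterol synthesis genes differed in both directions. A shift of the whole SREBP2 programme, the main activator of these genes, is consistent with a median of 0.46 over 8 target genes fixed beforehand, 7 of which rose and 1 of which fell, and the median was 0.46 to 0.51 under other scalings. For the genes that fell, copy number of whole runs is argued against as a shared cause, since 1 of 4 (MSMO1, on chromosome 4) lay in a called run that fell. EBP and SC5D lay in uncalled runs with medians of 0.15 and 0.10. TM7SF2 lay in a run that leaned downward (median -0.18, 25 genes lower and 6 higher) and narrowly missed the call (camera adjusted p = 0.0599). For TM7SF2 copy number therefore stays open. A raised SREBP2 programme is a hypothesis found and tested on the same libraries, and an effect of EZH2 loss or of the clone on it was not separated.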
